A study of Mus musculus with 12 samples.

How the data were processed

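Total RNA from the hippocampus of 12 mice was labelled with Cy3 by the Low Input Quick Amp protocol and hybridised to 1-colour Agilent arrays, 1 mouse per array. Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.3.1, and the processed signal is an intensity after background subtraction and detrending within each array, with no scaling between arrays. Per the file headers the probe coordinates are on mm9. The deposited value table holds log2 values, and its columns share nearly the same distribution (medians 5.369 to 5.370); the step that made it is not stated. Each of its columns correlated best with the processed signal of the array it is named for (r from 0.990). The per-array intensities were analysed here, and the deposited table served as an alternative. Per the file headers the other columns used were the flags of each spot (other, 0 or 1) and the intensity of the local background.

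The arrays lay on 3 slides, each with 1 array per circadian time. Each circadian time had the same array position on every slide, so position and circadian time cannot be told apart. The signal over background gives the depth: between 59.3% and 77.1% of the 59305 non-control spots per array lay well above background, and 0 spots were saturated. The local background of CT0 mouse 1 was 100, against 25 to 37 on the other arrays. Per the file headers the quality result of that array was to be evaluated, and in range for the others. For arrays the number of mice limits the precision.

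Values were log2 processed signal minus the array's 75th percentile over non-control probes. Spots marked as outliers were left out and the spots of a probe were averaged. Of 55681 non-control probes, 146 lacked a value on some array, and 33965 were kept because all 3 arrays of at least 1 circadian time lay well above background. The probe with the highest mean stood for its gene, which left 24089 genes. Names were updated through a RefSeq table (assembly GRCm38.p6), whose coordinates were not used: 26582 probes matched by accession, 2602 by symbol and 492 by synonym, and 26005 kept the array's own name.

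R 4.3.3 with limma 3.58.1 was used. One fit gave a mean for each circadian time over the 12 arrays. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes) by the moderated F test on the 4 means, by the F test on a cosine and a sine of 24 hours, and by limma's moderated statistic for each of the 6 pairs of times, each pair adjusted on its own. The limma test camera compared gene lists with the other genes for CT12 against CT0 and CT18 against CT6, with a preset inter-gene correlation of 0.01 and, beside it, an estimated one, adjusted over 35 lists. Fisher's exact test, two-sided, compared the share of called members with that of the other genes, and 10000 random lists matched in intensity gave the percentile of each list. The lists, 17 of processes and 18 of cell types or tissues, were written from general knowledge. A further 3 lists for parts of the brain were written after the leading genes of CT12 mouse 11 were seen. Where 1 group was not well above background on any array, a fold was given as a lower bound, with each dim array set at the level of its dimmest probe well above background, or at its own value where that was higher.

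The tests, lists, alternatives and the rule for named genes were chosen before the data were examined, apart from those said to be chosen later. The rule named all measured members of 3 clock lists, up to 20 further genes with the largest range among those called by the F test, and up to 8 higher and 8 lower genes per pair of opposite times. It also named the 4 members with the smallest F test p of each process list and 10 of the intellectual disability list. Other genes are said to be named after their values were seen. Some genes that the rule names are not reported here.

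The procedure was tested on simulated data with 24089 genes and 3 mice per time, in which 50 genes per fold size were changed. The F test recovered 26% of changes of 1.5-fold, 46% of 2-fold, 80% of 3-fold and 84% of 4-fold, with 5 unchanged genes among 123 called. The rhythm test recovered 16%, 46%, 78% and 78%, with 8 unchanged among 117. For CT12 against CT0 the shares were 24%, 50%, 74% and 90%, and for CT18 against CT6 14%, 56%, 70% and 84%. Of the lists of 25 genes, camera with the preset correlation called 10 of 10 that were moved by 0.5 log2 and 0 of 10 that were not. Each gene was drawn on its own, without correlation between genes, slide effects or a library that stood apart. The simulation therefore cannot show how camera behaves where the genes of a list vary together.

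Alternatives to these choices were quantile normalization, median centring, normexp background correction, the deposited table, other filters and probe summaries, other variance models, slide as a block, a fit of only the 6 arrays compared, adjustment over all pairs, and leaving out each library in turn. Array quality weights, leaving out CT12 mouse 11 with slide as a block, and leaving out CT0 mouse 3 together with CT12 mouse 11 were added after the data were seen. Probes below the filter, control spots and transcripts without a symbol in the gene lists were left out.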

Results

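RNA from the hippocampus, the brain region that forms spatial and episodic memory, was measured in 12 adult male wild-type mice held in constant darkness. Each mouse had its own 1-colour Agilent array, with 3 mice at each of 4 circadian times: CT0 (start of the subjective day), CT6, CT12 (start of the subjective night) and CT18. The hours in darkness were 30 at CT18, 36 at CT0, 42 at CT6 and 48 at CT12. Of 59305 non-control spots per array, between 59.3% and 67.1% lay well above background on 11 arrays and 77.1% on CT0 mouse 3. Values for 24089 genes entered the tests, 16093 of them with a RefSeq symbol, and are given as log2 intensity relative to the array's 75th percentile. The number of arrays limits the precision of every value.

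The library labelled CT12 mouse 11 stood apart from the others. Its correlation with the other libraries across genes, which are not independent replicates, was 0.945 to 0.965, against at least 0.984 among the remaining 11. The excitatory neuron list (7 genes) had a median of -4.19 in it, relative to each gene's mean, and the CA1 pyramidal cell list a median of -2.69. The choroid plexus list, 10 measured genes of the tissue that makes cerebrospinal fluid, had medians of 3.85 in CT0 mouse 1, 3.46 in CT12 mouse 10, 2.72 in CT6 mouse 7, 2.69 in CT18 mouse 14 and 1.87 in CT12 mouse 11. In the other 7 libraries its median lay between -2.36 and -1.87. The thalamus list reached 1.51 in CT12 mouse 10 and 0.63 in CT12 mouse 11, and the blood list 1.38 in CT12 mouse 11. Counts without CT12 mouse 11 stand beside those of each comparison, and leaving it out on its own was 1 of the 12 repeats that each omit 1 library.

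**Figure D1:**
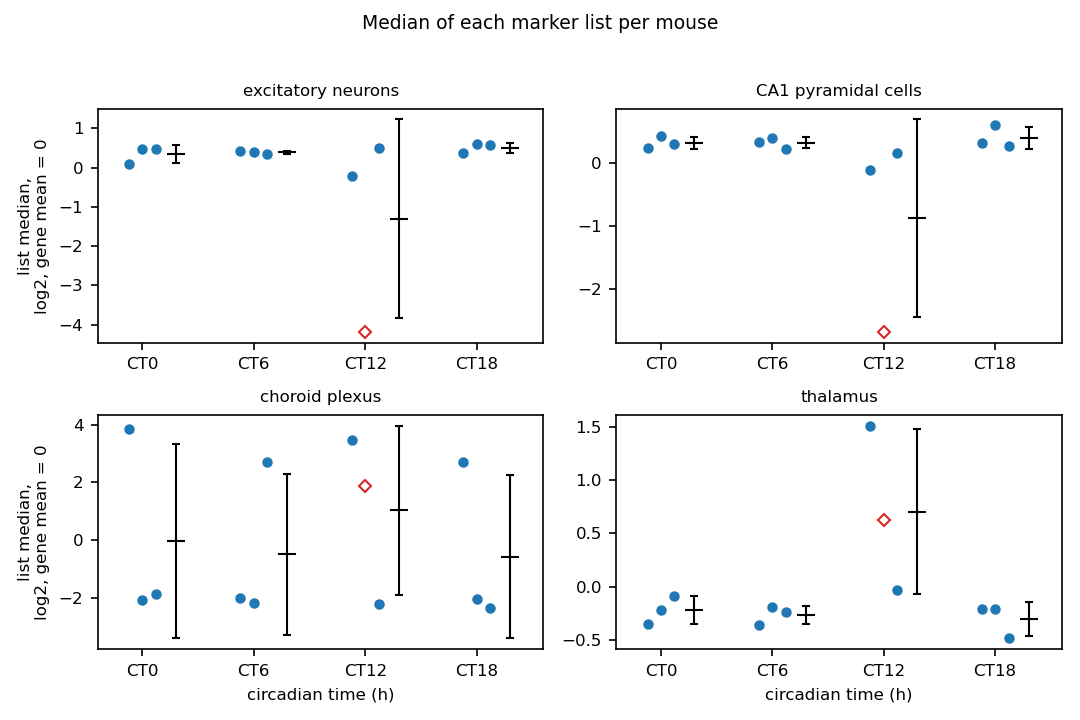
Median log2 intensity of each cell type or tissue list in each mouse (vertical axis, log2, mean of each gene over the 12 libraries set to 0) at the 4 circadian times (horizontal axis); filled circles are mice, the open diamond is CT12 mouse 11, and bars give mean and SD of the 3 mice. The excitatory neuron median of CT12 mouse 11 was -4.19, and the choroid plexus median lay between 1.87 and 3.85 in 5 libraries and between -2.36 and -1.87 in the other 7.

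The first comparison asked which hippocampal genes vary with circadian time. Genes of the clock, chaperones of the endoplasmic reticulum (ER) and genes that respond to glucocorticoid hormones led the genes that differed. Ciart, a repressor of CLOCK and BMAL1, had its lowest mean at CT0 (-3.68 ± 0.29, SD, n = 3) and its highest at CT12 (-1.82 ± 0.10). Its probe lies on mm9 chromosome 3 at 95682433 to 95682492. Nr1d1, which encodes the repressor REV-ERB alpha, was highest at CT6 (1.04 ± 0.10) and lowest at CT18 (-0.07 ± 0.12). Per2, which encodes a repressor of the same loop, was lowest at CT6 (-1.46 ± 0.06) and highest at CT18 (-0.58 ± 0.08). Dbp, a transcription factor that binds D-box elements, went from 4.31 ± 0.24 at CT0 to 5.69 ± 0.20 at CT12. Adjusted p values from limma's moderated F test were 0.0095 for Ciart, 0.0191 for Nr1d1, 0.0463 for Per2 and 0.0484 for Dbp. Leaving out CT12 mouse 11 gave 0.0138, 0.0117, 0.033 and 0.0611, and with slide as a block 0.0184, 0.0149, 0.0744 and 0.0699. Arntl, which encodes the activator BMAL1, had means of 1.41 ± 0.19 at CT0 and 0.71 ± 0.09 at CT12 and did not pass (adjusted p = 0.111). Nr1d2, the paralog of Nr1d1, passed without CT12 mouse 11 (0.031) and not with it (0.0939).

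**Figure D2:**
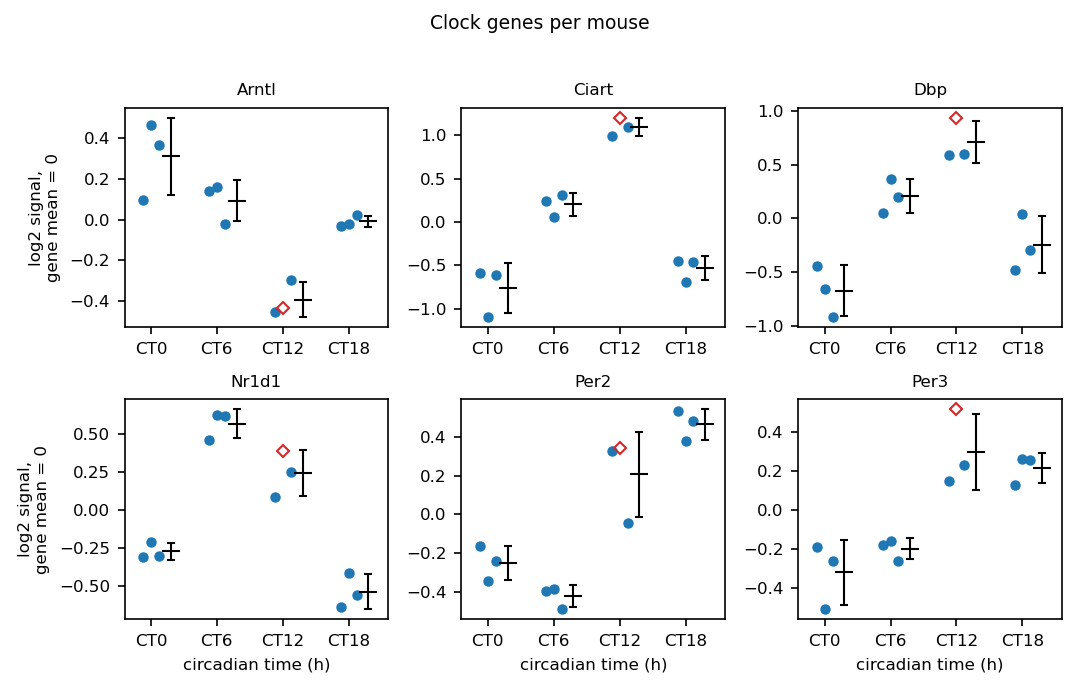
Log2 intensity of 6 clock genes (vertical axis, log2, mean of each gene set to 0) at the 4 circadian times (horizontal axis) in 3 mice each; filled circles are mice, the open diamond is CT12 mouse 11, and bars give mean and SD of the 3 mice. Ciart and Dbp were lowest at CT0 and highest at CT12, Nr1d1 was highest at CT6 and Per2 at CT18; Arntl and Per3 did not pass the test (adjusted p = 0.111 and 0.139).

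Among the ER chaperones and genes of the unfolded protein response, 6 of 24 differed among the times. These were Hspa5, Pdia3, Pdia6, Sdf2l1, Manf and Creld2, and 16 differed when adjusted over the list alone. Glucocorticoid-responsive genes gave 5 of 25 (Sgk1, Tsc22d3, Plin4, Hif3a and Arrdc2; 9 when adjusted over the list alone), and core clock repressors 3 of 10 (Ciart, Nr1d1 and Per2; 7 when adjusted over the list alone). The share of called genes in these lists exceeded that of the other genes by Fisher's exact test, two-sided, with adjusted p = 6.52e-11, 8.84e-09 and 5.89e-06. The values were 4.29e-12, 4.61e-06 and 1.18e-07 without CT12 mouse 11, and 0.00132, 1.92e-05 and 0.000325 with slide as a block. Fisher's exact test takes genes as independent, although members of a list can vary together in the same mice. Its p values therefore do not measure the spread between mice. The other genes also included transcripts without a RefSeq symbol. Of the 40 called genes 39 had such a symbol, against 16093 of the 24089 tested. With the block fewer members were called: 2 ER chaperones (Hspa5 and Sdf2l1), 3 glucocorticoid-responsive genes (Tsc22d3, Plin4 and Arrdc2) and 2 repressors (Nr1d1 and Ciart). Adjusted over the list alone they were 16, 10 and 7. A pair of further groups passed the same test: immediate-early genes with 2 of 29 (Maff and Inhba; adjusted p = 0.00928; 3 over the list alone) and cold-inducible RNA-binding proteins with 1 of 4 (Cirbp; adjusted p = 0.0464; 3 over the list alone). Neither passed without CT12 mouse 11, where immediate-early genes had 1 called (adjusted p = 0.343) and cold-inducible RNA-binding proteins 1 (0.0854). With slide as a block immediate-early genes had 0 called by limma, 2 when adjusted over the list alone, and did not pass, while cold-inducible RNA-binding proteins did (0.0232). Heat shock genes (1 of 21, adjusted p = 0.157) and clock-controlled outputs (1 of 22, adjusted p = 0.157) did not, with 6 and 8 called when adjusted over the list alone. Other genes with a large range were Plin4, a coat protein of lipid droplets (adjusted p = 0.0257), Ada, which encodes adenosine deaminase (0.0188), Derl3, a factor of ER-associated degradation (0.0444), and P4ha1, a collagen hydroxylase.

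The moderated F test called 40 of 24089 genes, and 31 of them also without CT12 mouse 11, where the count was 59. The highest mean fell at CT18 for 22, at CT12 for 14, at CT6 for 4 and at CT0 for 0 (36, 13, 8 and 2 without that library); the lowest fell at CT6 for 18 (32 without it). With slide as a block 16 genes passed, 13 of them shared. Leaving out CT0 mouse 1, 2 or 3 left 6, 10 or 4 genes, and leaving out CT12 mouse 10 or 12 gave 22 or 117. Without CT18 mouse 15 or 16 the counts were 14 and 6. The limma test called 0 genes without CT6 mouse 5, 6 or 7 or CT18 mouse 14, where 2015, 1804, 1853 and 2056 genes had an unadjusted p under 0.05. The lists with a raised share, 5 with all libraries, numbered 0 in those 4 cases, 2 without CT0 mouse 1, 2 or 3 or CT18 mouse 16, and 3 without CT12 mouse 10, 11 or 12.

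The second comparison fitted a 24-hour cosine to the same values, to place the peak of each rhythm. The fitted cosine peaked at 10.6 h for Ciart (adjusted p = 0.0134) and 10.8 h for Dbp (0.0343). It peaked at 7.67 h for Nr1d1 (0.0108) and 16.2 h for Per2 (0.0343). Mice were sampled only every 6 hours, and no error was estimated for these peak times. The adjusted p values are for the 24-hour rhythm, not for its peak time. Fam83d, a mitotic spindle gene, also passed (adjusted p = 0.0121). The test called 17 genes, whose peaks fell in each of the 4 intervals of 6 hours (2, 6, 4 and 5 from CT0 onward). Without CT12 mouse 11 it called 68, among them all 17, with 15, 18, 12 and 23 in those intervals, and with slide as a block 13. The counts were 4, 4 and 5 without CT0 mouse 1, 2 or 3, and 7, 5 and 5 without CT6 mouse 5, 6 or 7. Without CT12 mouse 10 or 12 they were 3 and 5, and without CT18 mouse 15 or 16 they were 7 and 6. Without CT18 mouse 14 limma called 0, with 1788 genes at an unadjusted p under 0.05. With 4 times over 1 cycle, a 24-hour term cannot be told apart from hours in darkness.

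Between the start of the subjective night and that of the subjective day, CT12 against CT0, the question was which genes oppose these phases. Core clock repressors and glucocorticoid-responsive genes were higher at CT12. Ciart rose by 1.86 ± 0.15 (SE, n = 3 per time; 3.63-fold; adjusted p = 0.00424). Dbp rose by 1.38 ± 0.17 (2.61-fold; 0.0383). Tsc22d3, which encodes the anti-inflammatory mediator GILZ, rose by 1.26 ± 0.13 (2.39-fold; 0.0236), and Sgk1, a kinase induced by corticosteroids, by 1.58 ± 0.20 (2.99-fold; 0.0432). Hif3a, a hypoxia-inducible factor, rose by 2.08 ± 0.23 (4.22-fold; 0.0236), although its 3 probes ranged from 0.04 to 2.08. Plin4 rose by 2.07 ± 0.27 (4.19-fold; 0.0432), Arrdc2, an arrestin-domain gene, by 1.21 ± 0.14 (0.0236) and Ada by 1.26 ± 0.14 (0.0236). Fam83d rose to at least 1.52-fold its CT0 level (0.0281). Pcdh12, a protocadherin of blood vessels, fell by 1.27 on the log2 scale (± 0.17, adjusted p = 0.0432). The set was completed by Slc2a1 (0.0432) and by Cables1 and Nfkbia (both 0.0432), named after their values were seen, and 1 transcript without a symbol.

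As a group, the 10 core clock repressors had a median of 0.55 (1.47-fold) and all 10 lay above 0 (camera, adjusted p = 4.25e-12; adjusted p = 0.0248 with an estimated correlation). The 25 glucocorticoid-responsive genes had a median of 0.41 (1.33-fold), with 20 above 0 and 7 called, or 11 when adjusted over the list alone (2.22e-13; adjusted p = 0.0248 with an estimated correlation). Within the 3 slides the medians were 0.51, 0.83 and 0.47 for repressors and 0.52, 0.32 and 0.49 for glucocorticoid-responsive genes. With slide as a block the adjusted p values were 5.45e-10 and 6.46e-11. The medians were 0.48 and 0.37 without CT12 mouse 11. The glucocorticoid list shares Per1 with the repressors, Tsc22d3 and Klf9 with the clock-controlled outputs, and Dusp1 with the immediate-early genes. Clock-controlled outputs had a median of 0.32 (1.56e-05; adjusted p = 0.147 with an estimated correlation), which was 0.17 without CT12 mouse 11. Cold-inducible RNA-binding proteins had a median of 0.56 (0.000826; adjusted p = 0.204 with an estimated correlation) and D-box and ROR factors 0.18 (0.00781; adjusted p = 0.147 with an estimated correlation). The latter was 0.06 without CT0 mouse 1 and 0.29 without CT12 mouse 11. Core clock activators had a median of -0.48, with 0 of 4 above 0 (0.00502; adjusted p = 0.255 with an estimated correlation), which was -0.16 without CT12 mouse 11. ER chaperones gave a median of 0.01 and a mean of -0.02 (adjusted p = 0.495), and heat shock genes a median of -0.09 (0.224), which passed without CT12 mouse 11 (-0.11; 0.0344).

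**Figure D3:**
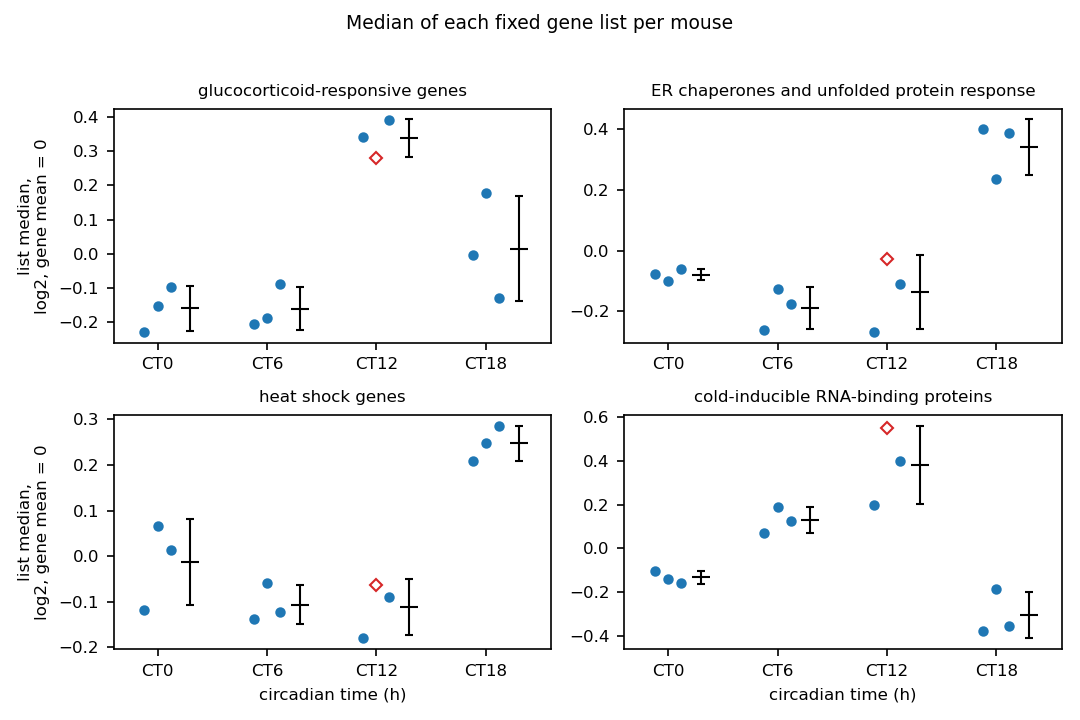
Median log2 intensity of gene lists in each mouse (vertical axis, log2, mean of each gene over the 12 libraries set to 0) at the 4 circadian times (horizontal axis); filled circles are mice, the open diamond is CT12 mouse 11, and bars give mean and SD of the 3 mice. ER chaperones lay at 0.40, 0.24 and 0.39 in the CT18 mice and at -0.26, -0.13 and -0.18 in the CT6 mice, and glucocorticoid-responsive genes at 0.34, 0.28 and 0.39 in the CT12 mice and -0.23, -0.15 and -0.10 in the CT0 mice.

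In this contrast 14 genes passed, 12 higher (85.7%) and 2 lower. With quantile normalization 7 passed, all higher, as with the deposited value table, and with median centring 9, all higher. With slide as a block 12 passed, 9 of them shared. Of the 11 called genes that the rule names, 8 kept their call with the block. All 14 had non-overlapping groups, as had 12.9% of all genes, against 10% by chance. Calling genes at this threshold selects for such a gap, so the gap adds no support to the calls. Without CT12 mouse 11 only 7 passed, and 4 of the 14 were among them, Ciart (0.015), Tsc22d3 (0.0359), Hif3a (0.0431) and Pcdh12 (0.0355). Without CT0 mouse 1 or 3 or CT6 mouse 5 or 6 the count was 1, without CT18 mouse 14 it was 2, without CT0 mouse 2, CT6 mouse 7 or CT18 mouse 16 it was 7, and without CT12 mouse 12 it was 78. Ciart passed in each of the 12 repeats that omit 1 library (adjusted p up to 0.0193), while Tsc22d3 was lost without CT0 mouse 1 or 3, CT6 mouse 5 or 6 or CT18 mouse 14 (up to 0.134). Hif3a passed in 6 (up to 0.138), Ada and Arrdc2 in 5 (up to 0.134 and 0.138), Sgk1 in 3 and Plin4 in 2 (both up to 0.213) and Dbp in 2 (up to 0.191); each of these was lost without CT0 mouse 1 and without CT6 mouse 5 or 6. The 17 lists that passed camera with the preset correlation were 14 to 17 across those repeats, which used that correlation alone.

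The middle of the subjective night against the middle of the subjective day, CT18 against CT6, addressed the same question for the other pair of opposite times. ER chaperones were higher at CT18. Sdf2l1, a partner of the ER chaperone system (probe on mm9 chromosome 16 at 17130426 to 17130485), rose by 1.83 ± 0.14 (3.55-fold; adjusted p = 0.00388). Hspa5, which encodes the chaperone BiP, rose from 4.06 ± 0.06 to 5.39 ± 0.11 (SD, n = 3; 2.52-fold; 0.00534). Manf, a secreted factor made under ER stress, rose by 1.15 ± 0.12 (2.23-fold; 0.00792), and Pdia3, a disulfide isomerase, by 0.74 ± 0.09 (0.0208). Derl3 differed by 1.21 ± 0.19 and passed only without CT12 mouse 11 (0.0512 with it, 0.0289 without). Chordc1, a partner of HSP90, rose by 0.85 ± 0.10 (0.0106). Cirbp, an RNA-binding protein induced by cold, fell 2.14-fold (SE 0.16 on the log2 scale; 0.0409). Among clock genes Nr1d1 fell by 1.11 (± 0.11; 0.00578) and Per2 rose by 0.88 ± 0.12 (0.0239). P4ha1 rose by 1.11 ± 0.15 (0.0242), Noxred1, an oxidoreductase gene, by 1.46 ± 0.16 (0.00931), H2bc6, a histone gene, by 1.25 ± 0.14 (0.0106), Scin, an actin-severing protein, by 1.24 ± 0.16 (0.0239) and Saysd1 by 1.05 ± 0.12 (0.0106).

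Genes that were lower at CT18 than at CT6 included Pla2g4e, a phospholipase (-1.53 ± 0.18; adjusted p = 0.0124), Slamf9 (-1.30 ± 0.19; 0.039), Lrrc29 (-1.20 ± 0.11; 0.00578) and Mri1, an enzyme of methionine salvage (-0.89 ± 0.13; 0.0409). Nxnl2, a thioredoxin-like gene, was at least 1.74-fold lower (0.0193). The 24 ER chaperone genes had a median of 0.54 (1.45-fold), with 22 above 0 and 6 called, or 16 when adjusted over the list alone (camera, adjusted p = 9.79e-26; adjusted p = 0.00612 with an estimated correlation). Its medians within the 3 slides were 0.63, 0.36 and 0.60 (5.48e-20 with slide as a block), and without CT12 mouse 11, 12 members were called. Heat shock genes had a median of 0.31 with 19 of 21 above 0 and 8 called over the list alone (3.58e-12; adjusted p = 0.0565 with an estimated correlation), and slide medians of 0.32, 0.23 and 0.39. Cold-inducible RNA-binding proteins had a median of -0.39, with 0 of 4 above 0 (4.36e-06; adjusted p = 0.084 with an estimated correlation), and slide medians of -0.44, -0.32 and -0.48. For their member Rbm3 the 3 probes ran from -0.42 to 0.61, and 2 shared the sign of the one used. Immediate-early genes had a median of 0.32 with 26 of 29 above 0 (3.13e-05; adjusted p = 0.795 with an estimated correlation), and 0.21 without CT18 mouse 15. Glucocorticoid-responsive genes had a median of 0.18 (0.00427; adjusted p = 0.639 with an estimated correlation) and did not pass without CT18 mouse 15 (0.08; 0.166). Cholesterol synthesis genes had -0.15 (0.00183; adjusted p = 0.795 with an estimated correlation) and did not pass without CT18 mouse 14 (-0.08). The dentate granule cell list had a median of 0.56, with 9 of 9 above 0 (0.00912; adjusted p = 0.795 with an estimated correlation). Core clock activators had a median of -0.09 although the test pointed upward (adjusted p = 0.728).

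Here 32 genes passed, 22 higher (68.8%) and 10 lower. The higher share was 81.1% of 53 with quantile normalization, the same counts with the deposited value table, and 79.2% of 24 with median centring. With slide as a block 40 passed, 23 of them shared. Of the 19 called genes that the rule names, 16 kept their call with the block. All 32 had non-overlapping groups, as had 22.8% of all genes, against 10% by chance. Calling genes at this threshold selects for such a gap, so the gap adds no support to the calls. Without CT12 mouse 11, 300 genes passed (192 higher and 108 lower), all 32 among them, and the median residual SD fell from 0.217 to 0.167. The count was 12 and 16 without CT0 mouse 1 or 3. It was 5, 7 and 1 without CT6 mouse 5, 6 or 7, and 7, 13 and 1 without CT18 mouse 14, 15 or 16. Sdf2l1 passed in each of the 12 repeats that omit 1 library (adjusted p up to 0.0374), while Hspa5 and Nr1d1 were lost without CT6 mouse 7 or CT18 mouse 16 (up to 0.0583 and 0.0671). Manf was lost without these and without CT6 mouse 5 (up to 0.0742). Chordc1 passed in 7 (up to 0.105), Pdia3 in 5 (up to 0.151), Per2 in 4 (up to 0.152) and Cirbp in 3 (up to 0.249), and each of these was lost whichever CT6 mouse was left out. ER chaperones, heat shock genes and cold-inducible RNA-binding proteins passed camera with the preset correlation in all 12 repeats. Their medians were 0.50 to 0.56, 0.26 to 0.35 and -0.44 to -0.36. An estimated correlation was not used in these repeats. With it, heat shock genes and cold-inducible RNA-binding proteins did not pass even with all libraries in the fit.

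The 4 pairs of times 6 hours apart in circadian time asked when in the cycle genes turn. The CT18 mice had 30 hours in darkness and the CT12 mice 48, so CT18 did not follow CT12 in darkness. That pair lay further apart in darkness than the others, and its circadian step cannot be told apart from hours in darkness. From CT12 to CT18 97 genes passed, 68 higher and 29 lower. Sdf2l1 rose by 1.55 (adjusted p = 0.00625) and Hspa5 by 1.11 (0.0151), while Ciart fell by 1.63 (0.00625), Ada fell by 1.56 (0.00625), Cirbp fell by 1.30 (0.0206) and Nr1d1 fell by 0.78 (0.0248). From CT6 to CT12 5 genes passed, all higher: Plin4, Tsc22d3, Arrdc2, Maff, a transcription factor induced early by stimuli and at least 3.04-fold higher, and Gm6277, named after its values were seen. Without CT12 mouse 11 Plin4 (0.0348) and Tsc22d3 (0.0394) passed, while Arrdc2 (0.102), Maff (0.0913) and Gm6277 (0.0726) did not; the counts were then 6 from CT6 to CT12 and 119 from CT12 to CT18 (90 higher and 29 lower). No gene passed between CT6 and CT0 or between CT18 and CT0 by limma (0 each), where 589 and 956 had an unadjusted p under 0.05. Without CT12 mouse 11, 5 genes passed between CT18 and CT0: Sdf2l1, P4ha1, Nxnl2, Wfdc6b and Zbtb40, the last pair named after their values were seen; 1 gene passed there without CT0 mouse 1 and 1 without CT0 mouse 2. With slide as a block, limma called 115 genes from CT12 to CT18 and 0 from CT6 to CT12 (3727 at an unadjusted p under 0.05). The CT12 to CT18 count was 33, 39 and 40 without CT0 mouse 1, 2 or 3, and 31, 14 and 16 without CT6 mouse 5, 6 or 7. It was 53 and 1260 without CT12 mouse 10 or 12, 8 and 17 without CT18 mouse 14 or 15, and 0 by limma without CT18 mouse 16 (2187 at an unadjusted p under 0.05). The CT6 to CT12 count was 3 without CT0 mouse 2 and 70 without CT12 mouse 12. It was 0 by limma without CT0 mouse 1 or 3, CT6 mouse 5, 6 or 7 or CT18 mouse 14, with 2545, 2564, 1816, 1428, 1795 and 2467 genes at an unadjusted p under 0.05.

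The title of the series asks whether genes of intellectual disability (ID) vary with circadian time. Of 190 ID genes listed from general knowledge, not from the study, 188 were measured. Slc2a1, which encodes the glucose transporter GLUT1 (probe on mm9 chromosome 4 at 118809864 to 118809923), was the 1 that differed among the 4 times (adjusted p = 0.0484). It rose from 2.79 ± 0.05 at CT0 to 3.57 ± 0.13 at CT12 (SD, n = 3; 0.77 ± 0.11, SE; 1.71-fold; adjusted p = 0.0432 for the pair). Its adjusted p for the pair was 0.0743 without CT12 mouse 11, and with slide as a block 0.0427; with each library left out in turn it passed in 1 of 12, where adjusted p ran from 0.0304 to 0.213. Hdac4, a histone deacetylase gene, differed by 0.47 ± 0.10 between CT18 and CT6 and passed only without CT12 mouse 11 (0.123 with it, 0.0416 without), as did Zeb2, named after its values were seen. In that pair limma called 3 of the 188 ID genes without CT12 mouse 11, these among them, and 0 with it. The voltage-gated channel genes Scn1a and Cacna1c, the adhesion gene L1cam, and Auts2, Gatm, Ids and Arhgef6 came next in the list by the F test and did not pass.

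The share of ID genes called, 0.532%, was set against 0.163% of the other genes (Fisher's exact test, two-sided, p = 0.269), and 1 was called when adjusted over the list alone. At an unadjusted p under 0.01 the shares were 4.79% and 3.20% (p = 0.209 by the same exact test), and 3.72% and 4.36% without CT12 mouse 11 (p = 0.857). The list's median -log10 p lay at percentile 99.1 of 10000 random lists matched in intensity, of which a share of 0.293 called as many genes. Both the other genes and the random lists included transcripts without a RefSeq symbol. Of the 40 called genes 39 had such a symbol, against 16093 of the 24089 tested. The median difference of the list was -0.06 from CT0 to CT12 (72 of 188 above 0; camera, adjusted p = 0.231) and 0.00 from CT6 to CT18 (96 above 0; 0.72). Once CT12 mouse 11 was left out, limma's F test called 0 ID genes (23 at an unadjusted p under 0.05). It also called 0 with slide as a block (33) and without each of the other libraries in turn (13 to 26 at an unadjusted p under 0.05) except CT12 mouse 12, where it called 2.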

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

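All tests of explanations in this part, and the counts over other splits of the samples, were chosen only after the result was seen. Among probes outside the comparisons, which were not well above background in all mice of any circadian time, 5946 were well above background on the array of CT0 mouse 3 alone. On CT12 mouse 10 alone 277 were, and on CT12 mouse 11 alone 304, against a median of 63 on the other arrays in each case. The array of CT0 mouse 3 also had 261 spots marked as outliers, against 121 to 167 on the others. Its slope over the spike-in controls was 0.901, against 0.932 to 1.02. No technical or biological explanation of these counts was tested.

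The library labelled CT12 mouse 11 differed from the mean of the other 11 by a median of -3.63 over the 13 genes of the excitatory neuron and CA1 lists, which share 1 gene. A source outside the hippocampus is consistent with this value, and with lists written after its leading genes were seen: with dim arrays set at the dimmest level well above background, a forebrain list had a median of -5.01 (12 genes), a cerebellum list 5.67 (12) and a hindbrain list 5.06 (9). Pcp2, abundant in Purkinje cells, stood 8.96 above the others, and Gabra6 of cerebellar granule cells was at least 744-fold higher. Hippocampus with an equal or smaller part of other tissue would lower the excitatory neuron list by at most 1 log2 unit, and it lay at -4.57 (-4.18 with dim arrays at that level), against a largest deviation of 0.65 in any other library. Poor RNA or hybridisation is argued against by 125 genes at least 8-fold above the other libraries, against at most 23 in any of these; whether the tube, the label or the dissection differed stays open.

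ER chaperones were higher at CT18 than at CT6, and 3 technical sources were weighed. Choroid plexus tissue is argued against as the source, though on few libraries. Among those whose choroid plexus median was below 0, the lowest CT18 list median lay 0.36 above the highest CT6 median. These were only CT18 mice 15 and 16 and CT6 mice 5 and 6, and groups so small often fail to overlap by chance. More dentate granule cells at CT18 stay open as a source: the ER chaperone median exceeded the granule cell median on 1 of 3 slides, with differences from -0.42 to 0.43. Array position cannot be told apart from circadian time, because both times kept their positions on all 3 slides. A 24-hour rhythm of protein folding in the ER and the 30 against 42 hours in darkness stay open, untested.

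Glucocorticoid-responsive genes were higher at CT12 than at CT0. The tissue of CT12 mouse 11 is argued against as the source by the list median of 0.37 that remained without it. More oligodendrocytes at CT12 stay open as a source: the list median minus the oligodendrocyte median was 0.21 and 0.34 on 2 slides and -0.30 on the slide of CT12 mouse 11, and without that library the 2 medians were 0.37 and 0.25. Array position cannot be told apart from circadian time here either, on all 3 slides. A daily rise of corticosterone before the active phase may underlie the difference, but no hormone was measured, and hours in darkness stay open as well.

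Other splits of the 12 samples into 4 groups of 3 were drawn, 100 with the real one. For genes differing among the 4 times 2 of 100 gave as many as the real 40; the other was a split with 52 genes. That split joined CT0 mouse 1, CT6 mouse 5 and CT18 mouse 14 of 1 slide, and CT6 mouse 6, CT12 mouse 11 and CT18 mouse 15 of another, so it partly follows the slides; with slide as a block the real count was 16. For the 24-hour rhythm only the real split gave as many as 17 (1 of 100, highest other 1). Splits that exchange times within slides only were drawn as well, 100 with the real one for each test. The real split alone gave as many genes by the F test (40, highest other 4). So it did by the F test with slide as a block (16, highest other 1). It alone gave as many for the rhythm (17, highest other 2) and for the rhythm with slide as a block (13, highest other 1). A share of 1 of 100 is the smallest that 100 splits can give. These tests used the same arrays, so they are not separate pieces of evidence. Pairs of times have 10 splits each, too few for a share under 0.05. The real counts and the highest other were 14 and 0 for CT12 against CT0, 32 and 0 for CT18 against CT6, 97 and 0 for CT18 against CT12, and 5 and 1 for CT12 against CT6. They were 0 and 0 for CT6 against CT0 and for CT18 against CT0 (589 and 956 genes at an unadjusted limma p under 0.05), where all 10 splits gave as many.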

How the results depend on the processing

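Array quality weights, leaving out CT12 mouse 11 with slide as a block, and leaving out CT0 mouse 3 together with CT12 mouse 11 were chosen only after the result was seen. The alternatives other than leaving out 1 library kept the direction and the call of 3 list results: core clock repressors (median 0.42 to 0.56, past the threshold in 14 of 14) and glucocorticoid-responsive genes (0.37 to 0.42, 14 of 14) from CT0 to CT12, and ER chaperones (0.46 to 0.56, 14 of 14) from CT6 to CT18; heat shock genes passed there in 13 of 14. Counts of single genes moved with most settings, and where no construction is named the cause was not tested. In the order F test, 24-hour rhythm, CT12 against CT0, CT18 against CT6, CT12 against CT6, CT18 against CT12, CT18 against CT0, lists with a raised share and intellectual disability (ID) genes, the reported counts were 40, 17, 14, 32, 5, 97, 0, 5 and 1. Leaving out CT12 mouse 11 with slide as a block gave 65, 121, 9, 664, 0, 49, 1, 3 and 0. Leaving out CT0 mouse 3 and CT12 mouse 11 gave an F count of 25, a rhythm count of 43, and 3, 291, 0 and 11 for the pairs up to CT18 against CT12, with 2 lists and 0 ID genes. Array quality weights, which gave CT12 mouse 11 a weight of 0.117, gave 1036 by the F test, 892 rhythms, and 2214, 20, 1200 and 15 for CT18 against CT6, CT12 against CT6, CT18 against CT12 and CT18 against CT0, 2 for CT6 against CT0 and 6 ID genes. Without a filter on dim probes, where more probes were tested, the counts were 2, 5, 1, 11, 0 and 3, with 2 lists and 0 ID genes. Quantile normalization and the deposited value table each gave 6 rhythms, 7 genes for CT12 against CT0, 53 for CT18 against CT6, 3 for CT12 against CT6 and 0 ID genes. Median centring gave 25 by the F test, 9 rhythms, 9 for CT12 against CT0, 3 for CT12 against CT6, 3 lists and 0 ID genes. Normexp background correction gave 11 rhythms, 53 for CT18 against CT6, 8 for CT12 against CT6, 167 for CT18 against CT12, 3 for CT18 against CT0 and 3 lists. An intensity trend with robust variance gave 27 rhythms, 68 for CT18 against CT6, 158 for CT18 against CT12, 3 for CT18 against CT0 and 3 lists. Without moderation of the variance there were 5 genes for CT12 against CT0, 108 for CT18 against CT6, 0 for CT12 against CT6, 182 for CT18 against CT12, 1 for CT18 against CT0 and 3 lists. Adjustment over all 6 comparisons gave 21 for CT18 against CT6, 8 for CT12 against CT6, 23 for CT18 against CT12, 4 for CT18 against CT0 and 1 for CT6 against CT0. A fit of only the 6 arrays compared, with fewer samples, gave 0 for CT12 against CT0, 59 for CT18 against CT6, 0 for CT12 against CT6 and 0 for CT18 against CT12. Probes well above background on all 12 arrays gave 65 for CT18 against CT6, 2 for CT12 against CT6 and 3 lists. Slide as a block gave 16 by the F test, 0 for CT12 against CT6 and 0 ID genes. An unadjusted F test p under 0.01 gave 9 ID genes. An estimated correlation, which widens the error of each list, left 2 of 17 lists for CT12 against CT0 and 1 of 7 for CT18 against CT6. Where limma called 0, the genes at an unadjusted p under 0.05 were 1974 (both libraries left out), 2571 (CT12 mouse 11 left out with slide as a block), 2598 (no filter), 2635 (no moderation) and 3727 (slide as a block) for CT12 against CT6, and 943, 1313 and 1949 in the fits of 6 arrays; for ID genes they were 41, 24, 17, 20, 14 and 33 with CT12 mouse 11 left out and slide as a block, both libraries left out, quantile normalization or the deposited table, median centring, no filter and slide as a block.

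With each library left out in turn, the counts ran from 0 to 117 for the F test, 0 to 68 for the rhythm, 1 to 78 for CT12 against CT0, 1 to 300 for CT18 against CT6, 0 to 70 for CT12 against CT6, 0 to 1260 for CT18 against CT12, 0 to 5 for CT18 against CT0 and 0 to 0 for CT6 against CT0. The lists past the threshold of camera with the preset correlation ran from 14 to 17 for CT12 against CT0. They ran from 6 to 10 for CT18 against CT6. Lists with a raised share ran from 0 to 4, and ID genes from 0 to 2. A few list medians from CT0 to CT12 changed sign, for which the cause was not tested. Immediate-early genes were at 0.10 with CT0 mouse 3 and CT12 mouse 11 left out (adjusted p = 0.842), against -0.60. With array quality weights blood was at -0.087 against 0.51, cytosolic ribosomal proteins at -0.039 against 0.05, and mitochondrial respiratory chain genes at -0.000655 against 0.13. Over the libraries left out, cytosolic ribosomal proteins ran from -0.11 (without CT12 mouse 12) to 0.13 and ependyma from -0.30 to 0.46 (without CT0 mouse 1). The median of all genes moved by over 0.1 only without a filter on dim probes (-0.12 for CT12 against CT0). Signal over background limits what can be called among dim genes, whose folds are lower bounds.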

Other observations

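The list comparisons of this part were planned, while array quality weights were chosen only after the result was seen. Oligodendrocyte genes, which make myelin, had a median of 0.35 from CT0 to CT12 with 10 of 10 above 0 (camera, adjusted p = 0.000138; adjusted p = 0.455 with an estimated correlation). It was 0.25 without CT12 mouse 11 (0.0048), and 0.31, 0.62 and 0.15 within the 3 slides. Genes of the respiratory chain in mitochondria had a median of 0.13 (40 of 43 above 0; 2.52e-05; adjusted p = 0.608 with an estimated correlation), which was -0.000655 with array quality weights and did not pass without CT12 mouse 12 (0.03; 0.0978). Cytosolic ribosomal proteins had 0.05 (0.0457; adjusted p = 0.768 with an estimated correlation), which was -0.039 with those weights and -0.11 without CT12 mouse 12 (0.0478), and did not pass without CT0 mouse 1 (0.02; 0.133) or 3 (0.07; 0.164). It was 0.13, 0.11 and 0.087 without CT12 mouse 10, CT12 mouse 11 or CT0 mouse 2. Cholesterol synthesis genes had 0.13 (0.00781; adjusted p = 0.608 with an estimated correlation) and did not pass without CT0 mouse 1 (0.08; 0.0856) or CT12 mouse 12 (0.06; 0.0838), and had 0.19 without CT12 mouse 10. Immediate-early genes, induced by neuronal activity, had a median of -0.60 (0.00401; adjusted p = 0.608 with an estimated correlation), and did not pass without CT12 mouse 11 (-0.20; 0.0598) or CT0 mouse 3 (-0.46; 0.164).

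Several lists from CT0 to CT12 moved with the library labelled CT12 mouse 11. Excitatory neurons had a median of -1.63 (0.00743; adjusted p = 0.608 with an estimated correlation), CA1 pyramidal cells -1.08 (0.00263; 0.608) and dentate granule cells -0.73 (0.00286; 0.592). Without that library excitatory neurons were at -0.17 (0.116), CA1 pyramidal cells at -0.23 and dentate granule cells at -0.34 (0.0048). Leaving out CT12 mouse 12 put CA1 pyramidal cells at -1.73, and leaving out CT12 mouse 10 put dentate granule cells at -1.17. Microglia were at -0.29 (0.00502; 0.608 with an estimated correlation) and at -0.08 without it (0.399). Blood was at 0.51 (0.00508; 0.608) and at 0.07 without it (0.518). The thalamus list was at 1.15 (0.000705; 0.464) and at 0.76 without it, but did not pass without CT12 mouse 10 (0.31; 0.118).

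The remaining lists did not pass from CT0 to CT12. Glutamate receptor genes were at -0.15 (adjusted p = 0.495), GABA receptor genes at -0.13 (0.543), genes of cAMP and MAP kinase signalling at -0.11 (0.228) and clock kinases and ubiquitin ligases at 0.04 (0.495). CA3 pyramidal cells were at -0.27 (0.259), oligodendrocyte precursors at -0.10 (0.495), astrocytes at 0.12 (0.214), endothelial cells at -0.06 (0.495) and pericytes and smooth muscle at -0.14 (0.451). Meninges were at -0.18 (0.496), choroid plexus at 1.01 (0.228), ependyma at -0.02 (0.975), and striatum at 0.09 (0.543). Interneurons had a median of 0.15 and a mean of -0.06 (0.495), and neocortex a median of 0.12 and a mean of -0.21 (0.495). Choroid plexus passed without CT0 mouse 1 (3.07; 0.000533) or CT12 mouse 12 (2.77; 0.0194), and ependyma without CT0 mouse 1 (0.46; 0.0424).

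From CT6 to CT18 the lists that did not pass included repressors of the core clock at 0.02 (adjusted p = 0.72), D-box and ROR factors at 0.10 (0.72), clock-controlled outputs at 0.02 (0.12) and clock kinases and ubiquitin ligases at 0.08 (0.165). Glutamate receptor genes were at -0.06 (0.72), GABA receptor genes at -0.06 (0.715), genes of cAMP and MAP kinase signalling at 0.02 (0.784), mitochondrial respiratory chain genes at 0.00 (0.715) and cytosolic ribosomal proteins at -0.00 (0.816). Excitatory neurons were at 0.11 (0.731), CA1 pyramidal cells at -0.04 (0.968), CA3 pyramidal cells at 0.35 (0.208), interneurons at -0.06 (0.915), astrocytes at 0.03 (0.715) and oligodendrocytes at 0.18 (0.222). Oligodendrocyte precursors were at 0.02 (0.715), microglia at -0.03 (0.819), endothelial cells at 0.01 (0.731) and meninges at -0.59 (0.0574). Pericytes and smooth muscle had a median of -0.01 and a mean of 0.01 (0.915). Choroid plexus was at -0.24 (0.968), ependyma at 0.37 (0.163), thalamus at -0.14 (0.755), neocortex at -0.09 (0.649), striatum at -0.61 (0.114) and blood at 0.38 (0.072). With 1 library left out, some of these passed. Meninges did so without CT0 mouse 1 (0.0283), CT6 mouse 5 (0.0123), CT12 mouse 10 (0.0478), CT12 mouse 12 (0.0447) or CT18 mouse 14 (0.000466). Blood did so without CT6 mouse 6 (0.0485), CT6 mouse 7 (0.020), CT12 mouse 10 (0.0171), CT12 mouse 11 (0.0358) or CT18 mouse 16 (0.00156). Striatum passed without CT6 mouse 5 (0.00995) or 7 (0.020), oligodendrocytes without CT6 mouse 5 (0.0277) or CT18 mouse 16 (0.0255), and ependyma without CT6 mouse 7 (0.0173). CA3 pyramidal cells passed without CT12 mouse 11 (0.0143), clock-controlled outputs without CT18 mouse 16 (0.0255) and mitochondrial respiratory chain genes without CT18 mouse 14 (0.0273).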
